A study of Mus musculus with 11 samples.

How the data were processed

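RNA was sequenced from dendritic cells of the mouse spleen. Per the labels' protocols, spleens of C57BL/6J mice aged 12 to 16 weeks were digested with collagenase, and dendritic cells were enriched by immunomagnetic removal of other cells with a kit for all dendritic cell subsets. Directional libraries were made from RNA bound to oligo(dT) beads. The series holds 5 libraries from mice heterozygous for a cysteine to phenylalanine change in uromodulin (UMOD C105F/+, replicates 2 to 6; the labels also write the change as C106F) and 6 libraries from wild type littermates (replicates 1 to 6). The labels give no sex, batch, day or injury for a mouse and do not say outright that each library came from its own animal, so p-values measure the spread between these libraries.

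FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1, StringTie 2.1.3b, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without their settings or order. The authors deposited 1 table with 417 gene rows, and 1 row per symbol. Every row had an absolute fold of at least 2 (smallest 2.0009) and an unadjusted p under 0.05 (largest 0.0493) in the comparison of C105F/+ with wild type. The table is therefore a selection made on the comparison itself, and other expressed genes were not analysed here. Read counts per library are given as deposited, without normalization, per the file headers. FPKM values and log2 normalized values per library were also made by the authors; the transformation behind the log2 values is not given in the sources used here, and they look like a regularized logarithm. The deposited fold change is written with a sign, and the deposited standard error is on the log2 scale. A deposited score column equals the log2 fold change over that standard error. The authors' mean over all libraries is a signal value on the scale of counts divided by size factors. The deposited p-value and the Benjamini-Hochberg adjusted p-value are the authors' own; 122 rows carry no adjusted p, and these were left without one.

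Total counts per library are not in the table, and the sum over selected rows is not a depth. The size factors behind the deposited means were therefore recovered by linear algebra from the counts (largest relative error 4.7e-15). They ran from 0.615 in wild type 1 to 1.98 in C105F/+ 2 and give relative depth. Scaled counts below are counts divided by these factors. The number of genes behind the authors' adjustment, recovered from the smallest p and its adjusted value, was 12407. At the largest p in the table the authors' ranking had reached gene 2361, of which 295 are rows here, and the last row with an adjusted p under 0.05 had rank 455, of which 111 are rows here. Most of the genes ranked that high are outside the table, so enrichment of a gene list could not be tested.

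The counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, two-sided, with the recovered size factors, edgeR's own filter on low counts and Benjamini-Hochberg adjustment over the 321 rows left by the filter. Because the rows were selected on the same difference, no p-value from them is independent evidence, and the adjustment over 321 rows is too lenient as a statement about all genes. The authors' deposited adjusted p is therefore quoted beside it. Single genes and list scores were also tested with an exact two-sided permutation test over the 462 assignments of 5 of 11 libraries, whose smallest p is 0.0022, on log2(scaled count + 1).

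Before the data were examined, 26 gene lists were fixed by symbol. These were lists for cDC1, cDC2 and plasmacytoid dendritic cells, the CCR7 programme, chemokines and their receptors, adhesion and migration, efferocytosis, MHC class I, MHC class II, tolerance, inflammatory cytokines with NF-kB targets, interferon-stimulated genes, the unfolded protein response, immediate-early and heat-shock genes and the cell cycle. Further lists held markers of T cells, B cells, plasma cells, NK cells, macrophages, monocytes, neutrophils, basophils with eosinophils and mast cells, erythroid cells with megakaryocytes, and stroma with endothelium, and there was a list of sex-linked genes. For the 6 lists with at least 5 rows, the split into higher and lower rows was set against all other rows with Fisher's exact test (two-sided), adjusted over the 6 lists. For the 11 lists with at least 3 rows, a score per library was the mean z-score of log2(scaled count + 1) over the list's rows. Named genes follow a rule fixed at the same time. It takes the 12 higher and the 12 lower rows with the smallest edgeR p among those past an adjusted p of 0.05, the 3 highest and the 3 lowest folds among the rows tested by edgeR, and up to 4 members of each list by edgeR p. The first 2 parts leave out predicted genes and rows whose higher group mean lay below the 25th percentile of row means. A gene outside the rule is said to have been chosen after its values were seen. The rule gave 64 genes, of which 2 are not reported here by name or value and are part of the counts and list scores only.

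Gene positions come from RefSeq on GRCm38.p6, the assembly also called mm10. A transcript length is that of the longest GENCODE transcript linked to any of the row's RefSeq accessions. Of the 417 rows, 416 matched by gene number and 403 (96.6%) had a transcript length. The table uses no strand information that could be checked, and members of near-identical families (the Ear ribonucleases, the Bcl2a1 copies, histone genes) may share reads.

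The edgeR step was tested on simulated data, with counts drawn for these rows from their means and size factors and 200 rows changed by known folds. Of the rows that passed the filter, 19.4% of the 62 changed 2-fold and 75.3% of the 89 changed 4-fold were recovered, and 2 of 178 unchanged rows were called. The permutation step was tested on simulated counts of all 417 rows with an assumed dispersion of 0.1, not one estimated from the counts. There 100% of the 139 rows changed 4-fold with a mean of at least 20 and 2.3% of 217 unchanged rows had a p under 0.05. Some genes varied more than this within C105F/+, such as Prg2 (3526 ± 2553 scaled counts, SD), so the 100% does not describe the test on them. Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0, limma 3.58.1 on counts, FPKM and the deposited log2 values, thresholds, the replicate number as a block, and each library left out. An adjustment over 12407 genes, the same without wild type 4, and the scaling of the FPKM values were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.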

Results

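Spleen dendritic cells from mice heterozygous for the uromodulin change C105F were compared with dendritic cells from wild type littermates. Uromodulin is a protein made by the kidney tubule and released into urine and blood, and the series asks how a mutant form of it bears on dendritic cell migration, uptake of dying cells, tolerance and kidney repair. The data are read counts of 417 genes in 5 C105F/+ and 6 wild type libraries. The authors had kept these genes for an absolute fold of at least 2 and an unadjusted p under 0.05 in this comparison, so each gene below was selected for the difference it shows. Umod itself has no row among them, and the genotype could not be checked from it. Counts over these rows ran from 195414 in wild type 1 to 1198500 in C105F/+ 2, and the size factors, which give relative depth, from 0.615 to 1.98 in the same libraries.

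Among the deposited rows, more genes were higher than lower in C105F/+ dendritic cells. The authors' deposited table lists 253 genes as higher and 164 as lower, and its adjusted p was under 0.05 for 88 of the higher and 23 of the lower genes. By the authors' ranking at least 455 genes had an adjusted p under 0.05, of which 111 are rows here. The directions of the others are not known. The leading gene in the deposited table was Coro2b, a coronin that binds actin, with a log2 fold change of 2.81 and an adjusted p of 1.64e-07. Jchain, the chain that joins IgM and IgA into polymers, followed with 2.89 and 4.58e-06 in the authors' deposited table. Many of the largest folds belonged to genes with few counts. Mean scaled counts were under 10 in 82 rows, 24 rows had no count in any C105F/+ library and 15 had none in any wild type library. The groups did not overlap in 56 rows, 42 higher and 14 lower. Chance alone separates 5 from 6 libraries in 0.433% of assignments, a share that does not apply to rows chosen for their difference.

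**Figure D1:**
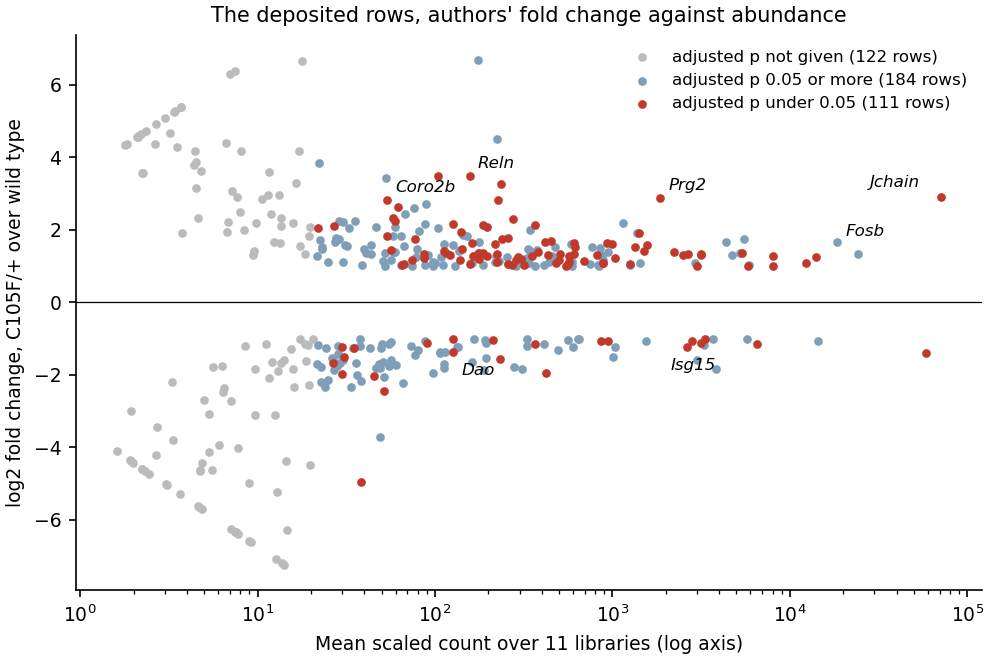
The authors' log2 fold change (C105F/+ over wild type, vertical axis) of each of the 417 deposited rows against its mean scaled count over 11 libraries (log axis). Red points are the 111 rows with an authors' adjusted p under 0.05, blue points have a larger one and grey points have none; the empty band around 0 is the authors' selection on a fold of at least 2.

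Among abundant genes, a mixed set was higher in C105F/+. Coro2b (Entrez 235431, chromosome 9, 62419490 to 62537044) had 100.4 ± 22.5 scaled counts in C105F/+ (SD, n = 5) against 14.3 ± 7.47 in wild type (SD, n = 6). This was a 6.97-fold difference (log2 2.80, SE 0.54, edgeR adjusted p = 0.0145, exact permutation p = 0.0022), and all 5 C105F/+ libraries lay above all 6 wild type libraries. Reln, which encodes a large secreted glycoprotein of the extracellular matrix (chromosome 5, 21884454 to 22344705), was 11.2-fold higher. Cacna1h, a T-type calcium channel subunit, was 7.10-fold higher, and Dusp18, a phosphatase, was 4.37-fold higher. Chst1, a sulfotransferase, had 386 ± 135 scaled counts against 115 ± 46.1 and was higher in 5 of 5 C105F/+ libraries than in any wild type library. The remaining genes with the smallest p were lymphocyte or granulocyte genes. These were Jchain, Cd28, Cr2, Ctla4, Derl3, Prg2 and Ear6, whose edgeR adjusted p ranged from 0.0145 to 0.0221. Among the rows tested by edgeR, which leave out genes with few counts, the folds of Ear6 (99.5), Ear1 (22.6, and 14.7 without C105F/+ 2; exact permutation p = 0.385) and Nlrp12 (13.7, and 8.4 without C105F/+ 2) were the highest 3, each resting on a wild type mean of at most 20.7 scaled counts and on libraries that ran from 0 upwards within C105F/+. Without wild type 4 the wild type mean was 0 for Ear6, 10.1 for Ear1 and 1.01 for Nlrp12, so the size of these folds rests on that library.

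Other genes were lower in C105F/+. Dao, D-amino acid oxidase (chromosome 5, 113999635 to 114025675), had 68.5 ± 17.2 scaled counts in C105F/+ against 176 ± 33.6 in wild type, which was 2.57-fold lower (edgeR adjusted p = 0.0245), with all 5 C105F/+ libraries below every wild type library. In the authors' deposited table its adjusted p was 1.49e-05. Cox17, a copper chaperone for cytochrome c oxidase, was 2.19-fold lower, and Cmc2, another small mitochondrial protein, was 2.11-fold lower. Mrc2, an endocytic receptor for collagen, was 2.22-fold lower (220 ± 63.4 against 488 ± 180). Bcl2a1a, an anti-apoptotic relative of Bcl2 with near-identical copies, was 2.24-fold lower, Fam89a 2.94-fold (1.82-fold without wild type 4) and Loxl4 3.44-fold lower. Among the rows tested by edgeR the lowest 3 folds were those of Timp1 (12.98-fold lower, 62.2-fold without C105F/+ 3, and 2.88-fold by the group means of 6.47 and 18.6 scaled counts without wild type 4; exact permutation p = 0.136), C2cd4b (8.10-fold) and the histone gene Hist1h4c (5.45-fold, and 2.75-fold with an edgeR adjusted p of 0.0525 without wild type 1; exact permutation p = 0.0671), and in each of them the wild type SD exceeded 0.5 times the wild type mean. Hist1h4c had 286 scaled counts in wild type 1 and 8.38 in wild type 4.

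By edgeR's quasi-likelihood test, 238 of the 321 rows that passed its filter had an adjusted p under 0.05, 170 higher and 68 lower. This count says little about the cells, because the rows were preselected. With the same edgeR p-values adjusted over the 12407 genes the authors had tested, no row passed (smallest adjusted p = 0.56, against 274 rows at an unadjusted p under 0.05 and 377 rows by DESeq2 over the table alone). That adjustment takes every gene without a row to have a larger p. The 0.56 is thus an upper limit, and whether a row would pass among all genes cannot be told. Of the 64 named genes, Coro2b, Jchain, Reln, Cacna1h, Cd28, Dusp18 and Prg2 had an edgeR adjusted p under 0.05 in each of the 11 fits that left out 1 library. The count of calls was 10 without C105F/+ 2, 14 without C105F/+ 5 and 15 without C105F/+ 6 (197, 196 and 204 rows at an unadjusted p under 0.05). Scaling on the selected rows themselves shifted the median log2 fold change by -0.73 to -0.96 and left 96 to 111 rows, 82 to 103 of them lower. Such a shift takes calls from higher genes near 2-fold and keeps those of lower genes. Calls under these scalings, given below for gene lists, therefore do not measure how firm a difference is.

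Genes of adhesion and migration were higher where they had a row. Of the 50 listed genes, 4 were rows of the table, among them Itgae, Itgal and Itga1. All 4 were higher, and all 4 had an adjusted p under 0.05 in the authors' deposited table. Itgae, the integrin chain that marks cross-presenting dendritic cells as well as some T cells (chromosome 11, 73090505 to 73147449), had 2355 ± 1046 scaled counts against 630 ± 311, 3.74-fold higher (edgeR adjusted p = 0.0228, also 4 of 4 genes adjusted over the list alone, and 0 of 4 under each of the 3 scalings on the selected rows). Itgal, a chain of the leukocyte integrin that binds ICAM proteins, had 17442 ± 6222 against 8207 ± 1958, 2.13-fold higher. Itgal is abundant in lymphocytes as well as dendritic cells, and the same libraries carried more lymphocyte transcripts. The list score was 1.40 higher in C105F/+ (exact permutation p = 0.0043, adjusted p = 0.0238 over 11 lists, 0.0524 without C105F/+ 2, 5 or 6, and 0.0582 without wild type 2, 3 or 6). Its rows had been selected for this difference, which favours a small p. Wild type 4 lay far below the other wild type libraries (score -1.91 against -0.46 to -0.17).

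Other programmes of dendritic cells were thinly represented. Of 50 chemokines and receptors, Xcl1, Ccr10 and Cxcr2 had rows, all higher (edgeR adjusted p = 0.0416, 0.0329 and 0.037; exact permutation p = 0.0628, 0.312 and 0.0779), 0 of 3 passed under the 3 scalings on the selected rows, and none had an adjusted p under 0.05 in the authors' deposited table. Ccr10 is a homing receptor of plasma cells and Cxcr2 one of neutrophils. Of 33 genes linked to tolerance, Ctla4 and Ahr had rows. Ctla4, an inhibitory receptor known best from T cells, had 219 ± 149 scaled counts against 49.3 ± 22.8 (4.44-fold higher, edgeR adjusted p = 0.0205). Ahr, a receptor for aromatic ligands, had 4123 ± 777 against 2056 ± 579 (2.00-fold higher, edgeR adjusted p = 0.0295), and 4 of 5 C105F/+ libraries lay above all wild type libraries. Under those scalings 0 or 1 of these 2 genes passed. The cDC1 list had 1 row of 16 genes (Itgae), and the plasmacytoid list had 1 of 20 (Pacsin1, 2.45-fold higher), neither past the threshold under those scalings. No row was found for the 48 efferocytosis genes, the 26 genes of the CCR7 programme, or the lists for cDC2, MHC class I, MHC class II, inflammatory cytokines, the unfolded protein response, the cell cycle, macrophages and sex-linked genes. Those genes were not analysed here. A change of under 2-fold in any of them, or a larger one with an unadjusted p of 0.05 or more, would not appear in the table.

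Interferon-stimulated genes were lower in C105F/+. All 6 listed genes with a row were lower: Isg15, Ifit1, Oas1g, Ifi27l2a, Xaf1 and Tgtp1. Against the other rows of the table, of which most were higher, this split had a Fisher's exact p of 0.0035 (adjusted p = 0.021), and it was the only one of the 6 lists tested to pass. The test counts genes that move together as independent, so its p does not measure the spread between libraries. It also favours lists of lower genes, since the 6 plasma cell rows, all higher, had a Fisher's exact p of 0.0856. Isg15, a ubiquitin-like protein induced by interferon (chromosome 4, 156199424 to 156200818), had 1515 ± 682 scaled counts against 3579 ± 1018, 2.36-fold lower (edgeR adjusted p = 0.0283, exact permutation p = 0.0043). Ifit1 was 2.38-fold lower, Oas1g 2.23-fold and Xaf1 2.11-fold lower. By edgeR 6 of 6 had an adjusted p under 0.05, over all rows and adjusted over the list alone, and 2 of 6 passed in the authors' deposited table. In 4 of the 5 C105F/+ libraries Isg15 was below every wild type library, while C105F/+ 3, with 2716 scaled counts, lay within the wild type range of 2564 to 5221. The same library also lacked the rise of plasma cell markers described below. The other 45 listed genes had no row.

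Immediate-early genes, which respond within minutes to tissue digestion and handling as well as to signals in the animal, were higher on average where they had a row. Of the 38 listed immediate-early and heat-shock genes, Fos, Fosb, Egr2, Egr3, Klf2 and Klf4 had rows, and the others were not analysed here. All 6 had a higher mean in C105F/+, but by edgeR only Egr2 (2.61-fold, adjusted p = 0.0295) and Klf4 (2.55-fold, adjusted p = 0.0308) passed, also when adjusted over the list alone. This count depended on the scaling, with 0 of 6 called under each of the 3 scalings on the selected rows and 6 of 6 under the scaling of the FPKM values. The direction of the list did not pass Fisher's exact test (adjusted p = 0.128). Fosb had 29524 ± 11038 scaled counts against 9338 ± 4846 (edgeR adjusted p = 0.0535, and 0.0059 without wild type 4), and by exact permutation all 6 genes had a p under 0.05 (0.0043 to 0.0281). Wild type 4 stood apart, with 44.0 scaled counts of Fosb against 9315 to 14224 in the other wild type libraries. Without that library the fold of Fosb was 2.64 instead of 3.16, and that of Egr2 was 2.26 instead of 2.61.

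Markers of other blood cells were higher in C105F/+ and varied widely between its libraries. All 6 plasma cell markers with a row, all 7 B cell markers and all 4 T cell markers were higher and passed by edgeR, and all passed under the scaling of the FPKM values. Under the 3 scalings on the selected rows, 1 of 6, 0 or 1 of 7 and 1 of 4 passed, and by exact permutation the plasma cell marker Mzb1 (p = 0.0628), the B cell markers Ms4a1 (0.0606) and Pou2af1 (0.0541) and the T cell marker Cd2 (0.0887) had a p over 0.05. Jchain (chromosome 5, 88519809 to 88527897) was by far the most abundant, with 134484 ± 76608 scaled counts against 18081 ± 3423, 7.44-fold higher (edgeR adjusted p = 0.0145, exact permutation p = 0.0152). It took 26.2% to 32.0% of the counts over these rows in C105F/+ 2, 4, 5 and 6, 4.53% in C105F/+ 3, and 4.19% to 9.27% in wild type. Mzb1, a chaperone of antibody secretion, was 2.99-fold higher. The B cell genes Cr2 and Fcer2a were 4.41-fold and 3.40-fold higher. Cd28, a costimulatory receptor of T cells, had 337 ± 159 scaled counts against 79.9 ± 25.8, 4.22-fold higher. Of the NK cell markers 5 had rows, 3 were tested and Eomes and Il2rb passed (4.72-fold and 3.59-fold, the latter 7.27-fold without wild type 4; exact permutation p = 0.0281 and 0.0974). Among neutrophil genes 4 of 5 passed, led by Retnlg (9.66-fold, and 17.8-fold without wild type 3), but Csf3r, Cxcr2 and G0s2 did not pass by exact permutation (p = 0.0563, 0.0779 and 0.119) and under the 3 scalings on the selected rows 0 or 1 of 5 passed; among basophil, eosinophil and mast cell genes Prg2, the eosinophil major basic protein, was 7.37-fold higher, whereas Mcpt1 did not pass (43 ± 26 against 99 ± 56). Ace and F13a1 of the monocyte list, Alas2 and Sptb of the erythroid list and Cdh5 and Flt1 of the endothelial list passed as well, with folds of 2.46 to 3.14. Of these, F13a1 (exact permutation p = 0.167), Alas2 (0.158) and Sptb (0.119) did not pass by permutation, no erythroid gene passed when adjusted over that list alone, and none of the NK cell, monocyte, erythroid or endothelial genes passed under the 3 scalings on the selected rows. None of the marker lists passed Fisher's exact test of direction (adjusted p = 0.128 for B cells and plasma cells, 0.162 for NK cells and neutrophils), since most other rows were higher too.

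**Figure D2:**
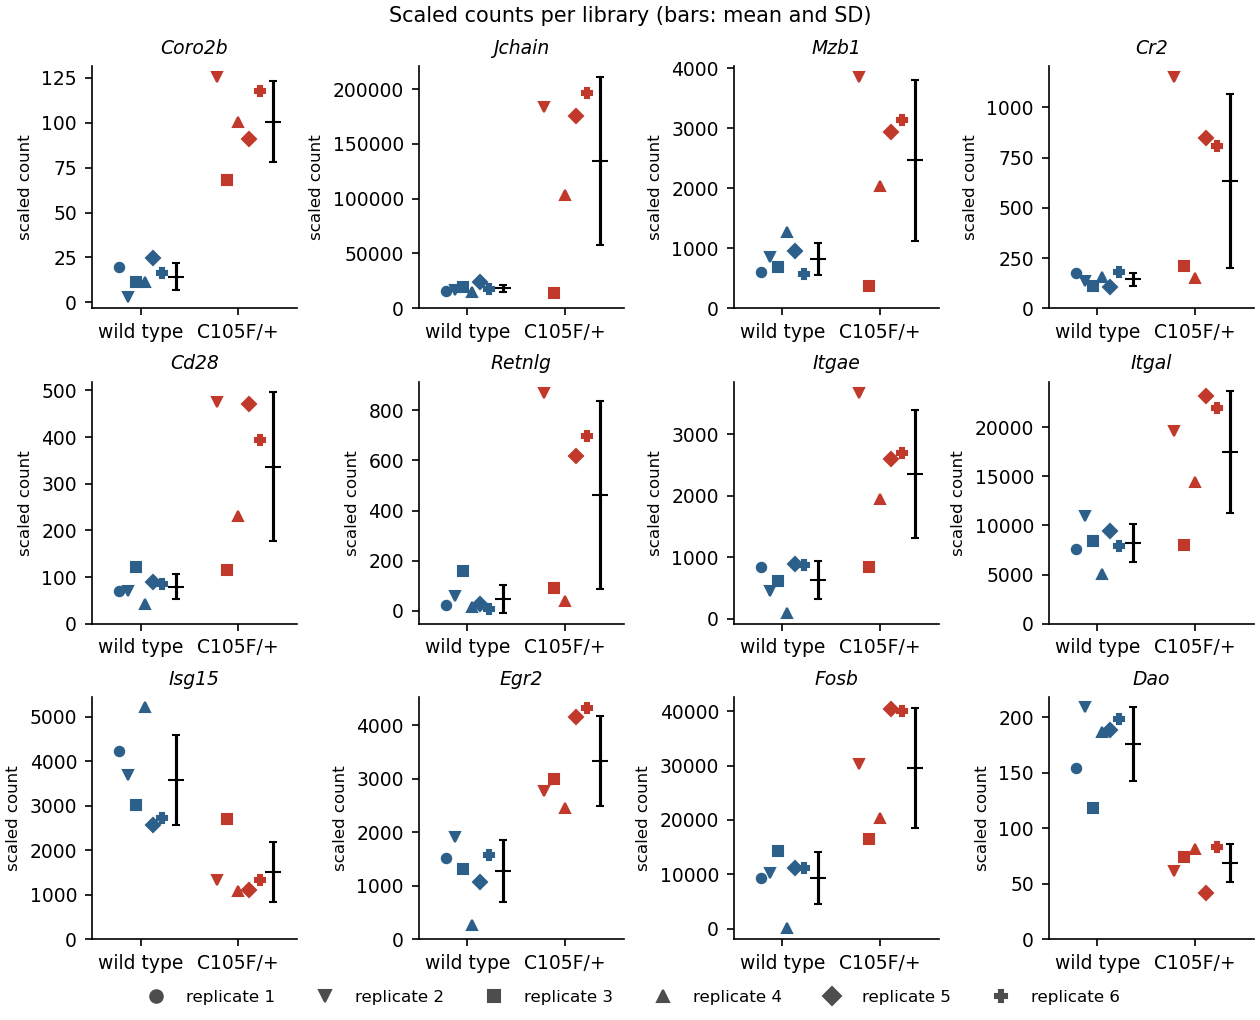
Scaled counts (counts divided by the recovered size factor) of 12 genes named in the text, 1 point per library, with marker shapes for replicate numbers and bars for the mean and SD (wild type n = 6, C105F/+ n = 5). All C105F/+ libraries lie above wild type for Coro2b, Egr2 and Fosb and below for Dao; C105F/+ 3 lies at or near the wild type level for Jchain (13489 scaled counts), Mzb1, Cr2, Retnlg, Itgae and Itgal, and C105F/+ 4 does so for Cr2 and Retnlg.

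In these genes C105F/+ 2, 5 and 6 resembled each other, and C105F/+ 3 and 4 stood apart. Log2 correlations among C105F/+ 2, 5 and 6 were 0.9728 to 0.9841, above every wild type pair (highest 0.9675). C105F/+ pairs that included C105F/+ 3 or 4 had 0.75 to 0.90. Of the 253 higher rows, 93.3% in C105F/+ 2, 96.1% in C105F/+ 5 and 92.1% in C105F/+ 6 lay above every wild type library, against 60.9% in C105F/+ 4 and 33.2% in C105F/+ 3. For the 164 lower rows the shares were closer, from 28.7% in C105F/+ 3 to 52.4% in C105F/+ 6. The plasma cell score was -0.85 in C105F/+ 3 and 0.76 to 1.39 in the other C105F/+ libraries, against -0.88 to -0.29 in wild type. A list score averages only rows that the authors had kept for their difference in this comparison. Small p-values were thus favoured in advance, and a score that passes is no independent evidence for its list. Of the 11 list scores, those for T cells (1.25 higher, exact permutation p = 0.0022), plasma cells (1.33, p = 0.0173), erythroid cells (1.15, p = 0.026), adhesion (1.40), immediate-early genes (1.11, p = 0.0065) and, in the other direction, interferon-stimulated genes (-1.34, p = 0.0087) had an adjusted p under 0.05. Those for B cells (1.17, adjusted p = 0.0536), NK cells (1.13, 0.0536), neutrophils (0.98, 0.0881), chemokines (0.94, 0.0881) and basophils, eosinophils and mast cells (0.51, 0.26) did not. Without C105F/+ 2, without C105F/+ 5 or without C105F/+ 6, none of the 11 scores passed (smallest adjusted p = 0.0524 in each case). With 1 library fewer a list that alone reaches the smallest possible p cannot pass the adjustment over 11 lists. That limit is not the whole reason for the misses. The adhesion, interferon and plasma cell scores had adjusted p of 0.0524, 0.0629 and 0.0629 without C105F/+ 2. Each had 0.0105 without C105F/+ 3, in a test of the same size. The scores themselves moved little without C105F/+ 2, 5 or 6 (adhesion 1.34 to 1.36, interferon-stimulated genes -1.32 to -1.29, plasma cells 1.24 to 1.25). How far the tests rest on these libraries is therefore not settled. In tests of the same size, without C105F/+ 3 the scores for B cells (adjusted p = 0.015), NK cells (0.0105), neutrophils (0.0314) and chemokines (0.015) passed as well, and without C105F/+ 4 those for B cells (0.0374), NK cells (0.0407) and neutrophils (0.0374) did. The plasma cell score, at 1.26 to 1.38, also missed the threshold without any single wild type library (0.0728 without wild type 1, 2, 3, 4 or 5 and 0.0998 without wild type 6), the erythroid score without wild type 2 (0.0655), 3 or 5 (0.0728), 4 (0.0764) or 6 (0.0998), the interferon score without wild type 1 or 2 (0.0698) or 3, 5 or 6 (0.0655), and the adhesion score without wild type 2, 3 or 6 (0.0582), while those for T cells and immediate-early genes passed in each of these 6 cases.

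**Figure D3:**
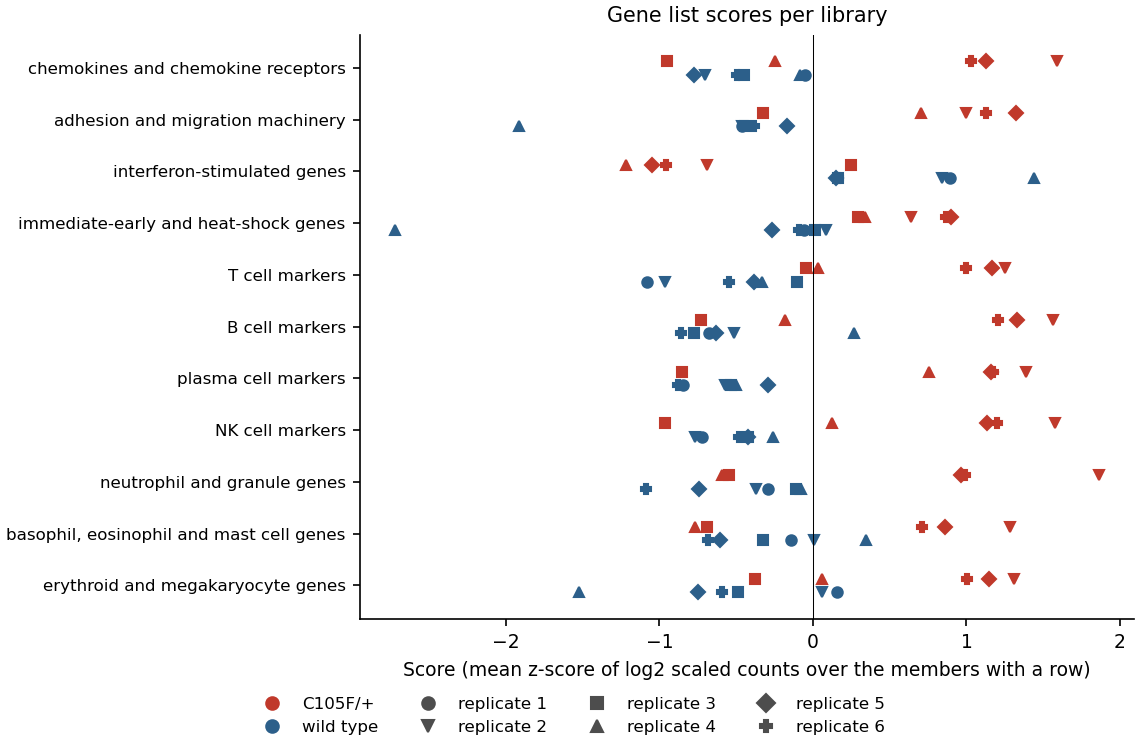
Score of each gene list per library (horizontal axis: mean z-score of log2 scaled counts over the list's rows), C105F/+ in red and wild type in blue, with marker shapes for replicate numbers. C105F/+ 2, 5 and 6 lie highest in the lists of other blood cells, C105F/+ 3 lies within or below the wild type range in all of them but T cells, and wild type 4 lies lowest for immediate-early genes (-2.72) and adhesion (-1.91).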

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

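The tests of explanations in this part were all chosen after the result was seen. In 150 groups of libraries (64 genes and 11 list scores in each genotype), the gap between the most extreme library and its neighbour was set against the range of the group. It was unusually wide 30 times, where chance gives about 1 in 20 groups. Wild type 4 accounted for 17 of these, C105F/+ 3 for 11 and wild type 1 for 2; genes that move together repeat the same fact.

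C105F/+ 3 had less of several genes that were high in the other C105F/+ libraries. It had 13489 scaled counts of Jchain (others 103802 to 196308), 365 of Mzb1 (2034 to 3862), 129 of Pou2af1 (1320 to 3354), 47.4 of Tnfrsf17 (192 to 321), 0 of Ccr10 (53.4 to 259), 74.9 of Cacna1h (455 to 595), 63.5 of Reln (267 to 425) and 275 of Flt1 (652 to 891). Its plasma cell score was -0.85 (others 0.76 to 1.39). It had more of 2 interferon-stimulated genes, with 2716 scaled counts of Isg15 (others 1092 to 1334) and 1368 of Ifit1 (302 to 458).

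Wild type 4 had less of the immediate-early genes, with 44.0 scaled counts of Fosb (other wild type libraries 9315 to 14224), 261 of Egr2 (1067 to 1920), 167 of Egr3 (2047 to 2658) and 485 of Klf4 (2538 to 4608), and a score of -2.72 (others -0.27 to 0.09). It also had less of Itgae (99.5, others 460 to 896), Pacsin1 (68.1, others 538 to 795), Cdh5 (18.8, others 210 to 324), Tnfrsf17 (8.38, others 52.0 to 94.1) and C2cd4b (0, others 13.4 to 28.8), and an adhesion score of -1.91 (others -0.46 to -0.17). It had more of Pou2af1 (1523, others 171 to 325), Fam89a (961, others 155 to 258), Bcl2a1a (18738, others 5123 to 8253) and Ear6 (21.99, others 0), and a B cell score of 0.27 (others -0.86 to -0.52). Wild type 1 had 0 scaled counts of Bcl11b (others 15.4 to 36.7) and of Reln (others 16.3 to 64.0).

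Markers of other cell types were higher in C105F/+. A single deep library is not the whole source: without C105F/+ 2, the deepest, the median log2 fold change of the 38 higher marker rows was 1.48, against 1.77 with all libraries. C105F/+ 5 and 6 resembled C105F/+ 2, so this does not test whether those libraries together carry the markers. More B-lineage cells in some preparations may account for the B and plasma cell part. Within groups the 13 markers of those lists rose and fell together with a mean pairwise correlation of 0.67, against a median of 0.33 in 10000 random sets of other higher rows of like abundance (99.99th percentile). The B cell and plasma cell scores were both high in C105F/+ 2, 5 and 6 and both low in C105F/+ 3. In C105F/+ 4, though, the plasma cell score was 0.76 and the B cell score -0.18. Such a correlation also cannot tell more cells from more transcript per cell. The isolation kit is meant to remove B-lineage cells, and whether a different yield of the isolation or a different spleen in C105F/+ mice lies behind their markers is open, since both follow the genotype labels.

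The 6 immediate-early genes with a row, of 38 immediate-early and heat-shock genes listed, were higher in C105F/+ on average. Wild type 4 alone is not the source. With scores taken over all 11 libraries, every C105F/+ library (lowest 0.29) lay above every other wild type library (highest 0.09). Recomputed without wild type 4, the score was 1.55 higher in C105F/+ (exact permutation p = 0.0079). Its unit then follows the smaller spread of the libraries left, so 1.55 is no rise over the 1.11 of all libraries. The folds fell without wild type 4, from 3.16 to 2.64 for Fosb and from 2.13 to 1.80 for Egr3. Whether the cells that carry B-lineage markers also carry these transcripts cannot be told apart from other sources. Within groups the immediate-early score and the B-lineage score had r = -0.077 over 11 libraries (permutation p = 0.786; rho = -0.01, permutation p = 0.989; r = -0.34 without the 2 libraries farthest out on the B-lineage score, C105F/+ 2 and C105F/+ 3), but r = 0.735 without wild type 4, the farthest on the immediate-early score (permutation p = 0.00975; rho = 0.73, permutation p = 0.0194), so the value rests on which library is left out. A difference in digestion or handling time between the genotypes could act on these genes and was not tested, because the labels give no times, and an effect of the genotype stays open for the same reason.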

How the results depend on the processing

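Of the alternatives below, the adjustment over 12407 genes, the same without wild type 4, and the scaling of the FPKM values were chosen after seeing the data. The 238 calls by edgeR became 102 with DESeq2 size factors estimated on the selected rows (12 higher, 90 lower), 111 with TMM on them (8 higher, 103 lower) and 96 with their totals (14 higher, 82 lower), against 170 higher and 68 lower with the recovered factors. These scalings moved the median log2 fold change by -0.76, -0.96 and -0.73, because they assume that most selected rows do not differ; the scaling of the FPKM values moved it by 0.16 and gave 242 calls. With each scaling on the selected rows 0 of the 4 adhesion genes and 6 of the 6 interferon-stimulated genes were called (4 of 4 and 5 of 6 with the scaling of the FPKM values). This contrast follows from the downward shift and does not show that the interferon result is the firmer. The DESeq2 Wald test gave 377 calls, and an adjusted p under 0.01 left 0. Adjusted over 12407 genes, edgeR called 0 rows with all libraries (274 at an unadjusted p under 0.05) and 0 without wild type 4 (249 at an unadjusted p under 0.05). These adjusted p are upper limits, because genes without a row were taken to have a larger p, so the absence of calls decides nothing. With 1 library left out, the calls ran from 10 (without C105F/+ 2) to 271 (without C105F/+ 3), with 14 without C105F/+ 5 and 15 without C105F/+ 6; the cause was not tested. Of the 64 named genes, 59 were called, and 7 were called in all 11 of these fits. Other filters, limma and the remaining thresholds stayed within 1.5 times of 238. Ppbp turned from higher to lower with TMM on the selected rows (log2 fold change -0.018), and 3 of the 238 calls, named here after their values were seen, also changed sign with it: Hip1 (1.00 to -0.041), Zbtb16 (1.03 to -0.024) and Tiam2 (1.02 to -0.044). Of the authors' 253 higher and 164 lower genes, 88 and 23 had an adjusted p under 0.05, and 115 and 99 had a fold of at least 3.

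With the replicate number as a block, edgeR called 0 rows (smallest adjusted p 0.0774, 167 rows at an unadjusted p under 0.05). The numbers do not appear to pair the mice: libraries of the same number had deviations that correlated at -0.05, -0.13, -0.14, 0.22 and -0.08, and 1 of 5 C105F/+ libraries correlated best with its own number. Differences within numbers gave list scores of 1.44 for adhesion, -1.28 for interferon-stimulated genes, 1.20 for immediate-early genes, 1.15 for T cells, 1.28 for plasma cells and 1.29 for erythroid cells, none past the threshold (exact adjusted p 0.172 to 0.229). With 5 pairs even the smallest possible two-sided p from sign changes lies above 0.05. No score could therefore pass, and the misses decide nothing.

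The direction of the 6 lists tested held in each alternative run, but leaving out a library changed the sign of no row, so those fits show nothing about stability. The median of log2 values in place of the mean z-score left the erythroid score short of the threshold (1.25, adjusted p 0.0804). With 1 library left out, list scores ranged from 0.77 to 1.38 for chemokines, 1.34 to 1.603 for adhesion, -1.52 to -1.29 for interferon-stimulated genes, 1.04 to 1.55 for immediate-early genes, 1.16 to 1.37 for T cells, 1.05 to 1.51 for B cells, 1.24 to 1.72 for plasma cells, 1.00 to 1.53 for NK cells, 0.80 to 1.24 for neutrophils, 0.34 (without C105F/+ 2) to 0.75 (without C105F/+ 4) for basophils, eosinophils and mast cells and 1.02 to 1.35 for erythroid cells. None changed sign. Without C105F/+ 2, 5 or 6, each of the 6 scores that had passed no longer did, and without 1 or more of the wild type libraries those for plasma cells, erythroid cells, interferon-stimulated genes and adhesion did not (adjusted p 0.0582 to 0.0998). The scores moved little, and with 1 library fewer no list can pass alone. Most scores passed without C105F/+ 3 or 4, in tests of the same size as without C105F/+ 2, 5 or 6. The size of the test is therefore not the whole reason for the misses without C105F/+ 2, 5 or 6. Of 100 splits of the 11 libraries into 5 and 6, 1, the real one, gave as many calls as 238, and the highest other gave 125; chance cannot be judged from this, because the rows were kept for their difference in the real split. Summing rows per symbol, or taking 1 row per symbol, moves nothing, since each symbol has 1 row.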

Other observations

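The tests in this part were chosen after the result was seen, except that of transcript length, whose outcome was not known when it was set; the gene families were picked by reading the table. Histone genes were lower in C105F/+ in all 9 rows (Fisher's exact test against the other rows, adjusted p = 0.0012 over 6 families). By edgeR 4 of the 9 had an adjusted p under 0.05, and 1 in the authors' deposited table. Because each family was noticed in the table first, its Fisher p describes genes chosen for that pattern. They encode the core and linker proteins of chromatin, and most of their messages carry no poly(A) tail. The summed scaled counts of the 9 were 1698 in wild type 1, 550 in wild type 2 and 362 in wild type 3, but 98.4 in wild type 4, 222 in wild type 5 and 239 in wild type 6, against 136 to 188 in C105F/+. Small RNA genes were lower in 8 of 9 rows (adjusted p = 0.0061) and predicted Gm genes in 12 of 14 (adjusted p = 0.0012), of which edgeR tested 2 and 8 and called 1 and 6, and of which 0 and 5 passed in the authors' deposited table.

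Genes of striated muscle were lower in all 5 rows (adjusted p = 0.0136). Myl7, a myosin light chain of the heart atrium, had no count in any C105F/+ library and 9.86 to 50.3 scaled counts in each wild type library. Myh7 and Tnnt2 were highest in wild type 4, with 219 and 109 scaled counts, and Myl10 had 142 there. Only 2 of the 5 were abundant enough for the edgeR test, and both passed by it. None of the 5 had an adjusted p under 0.05 in the authors' deposited table. Myl7 was given no adjusted p there, although its unadjusted p in the authors' own test was 5.18e-10. Zinc finger genes named Zfp (3 higher, 4 lower) and calcium channel subunits (3 higher, 1 lower) showed no common direction (adjusted p = 0.529 and 1). Malat1, a long nuclear RNA singled out after its values were seen, had 30843 ± 19088 scaled counts in C105F/+ (SD, n = 5) against 81548 ± 46314 in wild type (SD, n = 6).

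The lower rows that are histone and small RNA genes may reflect a difference between libraries in the recovery of short transcripts. Median transcript length was 3312.5 nt in 250 higher rows and 2057 nt in 153 lower rows, a log2 ratio of 0.69 (permutation p = 0.0001, the smallest that 10000 permutations can give), and 3342 against 2282 nt without histone and small RNA genes. The length difference was therefore not confined to those genes. This test takes rows that move together as independent, so its p does not measure the spread between libraries. Wild type 1, with the most histone reads, cannot be told apart from a group difference as the source: without it the median log2 fold change of the 9 histone rows was -0.72, against -1.61 with all libraries, between the values that would have decided it. A difference in RNA integrity or in cycling cells between the genotypes stays open, since the table holds no row of the cell cycle list and no measure of RNA quality.

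A segment of chromosome 7 carried along with the edited allele was a candidate explanation for part of the table. Umod lies on chromosome 7 (119462708 to 119479262, GRCm38.p6), and 2 rows, Itgal and Prss53, start within 10 Mb of it. Both are protein-coding, and 4.18 such rows would be expected there from the 377 protein-coding rows and the share of all protein-coding genes in that window (exact binomial p = 0.454). The numbers are too small to tell whether linkage contributes to either row.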
